A study of Homo sapiens with 8 samples.

How the data were processed

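RNA sequencing was done on SUDHL6, an established human germinal-centre B-cell-like diffuse large B-cell lymphoma line. Per the labels, cells were treated for 18 h with DMSO or with 2.5 µM of MS8815, EPZ-6438 or MS8815N, total RNA was column-purified, and libraries were made with either of 2 commercial kits, without saying which kit served which library. Each of the 4 groups had 2 libraries. The labels speak of duplicates and do not say whether these came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The submitters' processing notes name STAR 2.4.2, Salmon and GRCh38.

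The deposited values are 3 tables, one per compound, each with the same 2 DMSO libraries and the 2 libraries of that compound. The authors' values are on a log2-type scale, the variance-stabilising transform of DESeq2 according to the table names, made separately for each table. Over most of its range this transform is closer to a square root than to a logarithm, so a difference of the deposited values is not a log2 fold change. In the MS8815 table, for example, a doubling at the median gene equals 0.0586 units. The transform was therefore inverted to the normalised read count with its closed form. After inversion, the DMSO libraries of different tables differed by 1 constant per gene and 1 per library, with a largest deviation of 7e-11 on the log2 scale over 17219 genes. The deposited tables held 18744 genes for MS8815, 18320 for EPZ-6438 and 18398 for MS8815N, and 17467 genes were in all 3. No further filter was applied. Where 1 DMSO library was at 0 the gene's constant came from the other, and for the 10 genes of each joined table where neither gave one, the median constant of the table was used.

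The read depth of each library was estimated from the values. Normalised counts of low genes fall on whole multiples of the value of 1 read, which held for 41.7% to 63.7% of low values within a tolerance of 0.02 of a multiple, against 4% by chance. Depths in the report are these estimates. Replicates differed more than counting noise alone, with a median chi-square per gene of 1.4 to 2.28 in the 4 groups, so the fitted spread between libraries and not a counting interval was used for each comparison.

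Each compound was compared with DMSO within its own table of 4 libraries by limma 3.58.1 (R 4.3.3) with a trend in the prior variance, on the deposited values, with 2 residual degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes of the table, and a gene was called changed at an adjusted p under 0.05. Log2 fold changes and their standard errors came from limma on log2(normalised count + 1) of the same table. Means are normalised counts with the SD of 2 libraries. Compounds were compared with each other by limma on log2(normalised count + 1) of all 8 libraries, after each table was put on the scale of the MS8815N table with the constants above, with 4 residual degrees of freedom and 95% confidence intervals. The plan left comparisons between separately normalised tables untested. The joined fit was chosen after the data were examined, when the DMSO libraries were found to differ by constants only.

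Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 38 lists of at least 3 tested genes in each comparison. Camera compares a list with the other genes. An estimated correlation and fry, which tests whether a list moves on balance in one direction, served as alternatives. The 39 lists, the tests, the thresholds, the groups and most alternatives were fixed before the data were examined. A further 4 lists, of adherent-cell genes, immunoglobulin genes, non-polyadenylated RNA and aminoacyl-tRNA synthetases, were added after, and were adjusted as a family of their own. Counts of members that rose or fell refer to calls over all genes, and counts adjusted over the list alone are given beside them where they differ.

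Genes were named by a rule fixed before the data were examined. The rule takes 13 genes of EZH2 and sterol biology in each comparison (among them EZH2, EZH1, EED, SUZ12, SREBF2, HMGCS1, SQLE, INSIG1, CDKN1A, PRDM1 and MYC). It then takes up to 6 called genes with the largest rise and 6 with the largest fall, in the upper 50% of genes by level and with groups that do not overlap. It adds up to 4 members with the smallest p from each list described. Some genes that the rule takes are not reported here, and their values are left out of the counts of single-gene values under alternatives. Coordinates are those of GENCODE 29 on GRCh38, the build that the processing notes name. The gene model behind the deposited tables was not analysed here.

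Agreement between compounds was measured across genes by Pearson and Spearman correlation of the log2 fold changes over the 17467 shared genes, beside the value from 100 simulations of unchanged groups against shared controls, and by the overlap of calls. For the overlap, the simulated groups supplied as many top genes by difference over SD as were called. Genes are not independent replicates, so no p is given. The tests were also run on simulated data. With 50 genes per size, changes of 1.5-fold were recovered for 64% of genes in the EPZ-6438 table and 84% in the MS8815N table, but for 16% in the MS8815 table, and 2-fold changes for 98%, 98% and 58%. In the joined fits, 1.5-fold changes were recovered for 78% to 88% of genes. At most 1.2% of calls were false. These simulations changed 200 genes and gave all genes 1 dispersion, taken from the DMSO libraries (0.00105 to 0.00161). The MS8815 replicates differed more than the DMSO replicates (median 0.143 against 0.083 on the log2 scale). The rates of recovered and false calls therefore need not hold for the real comparisons.

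Alternative settings fixed before were quantile normalisation, removal of the lower 50% of genes, limma without trend, a replicate term, stricter thresholds, leaving out each library in turn, an estimated inter-gene correlation and fry. Chosen after the data were examined were fits on log2(normalised count + 1) with pseudocounts of 1, 0.1 and 5, the joined fit for comparisons with DMSO, the removal of the MS8815 libraries, a filter at a mean normalised count of 50 for the agreement, and a scaling to B-cell genes. The last rescaled the treated libraries so that B-cell genes with a normalised count of at least 200 in the reference group had a median log2 fold change of 0. Calculations and plots used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. No library was left out of the results given first.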

Results

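Transcript levels were measured by RNA sequencing in 8 libraries of SUDHL6 lymphoma cells, 2 each for the DMSO vehicle, MS8815, EPZ-6438 and MS8815N. The labels describe MS8815 as a PROTAC (a molecule that recruits a ubiquitin ligase to degrade its target) against EZH2, the histone H3K27 methyltransferase of polycomb repressive complex 2. EPZ-6438 (tazemetostat) is described as the matched inhibitor of the EZH2 enzymatic domain, and MS8815N as a non-PROTAC analog control. All compounds were given at 2.5 µM for 18 h. The estimated depth was 30.8 to 31.7 M reads for the DMSO libraries across the tables, 30.5 and 26.0 M reads for EPZ-6438, and 34.1 and 30.2 M reads for MS8815N. The MS8815 libraries had fewer reads, 13.0 and 14.6 M reads, and a larger difference between replicates (median 0.143 on the log2 scale, against 0.079 to 0.085 in the other groups).

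The comparison of MS8815 with DMSO asks what an EZH2 degrader does to the transcriptome of these cells. The MS8815 libraries limit the answer, since genes of adherent cells rose strongly in them and B-cell genes stood at 49.9% of DMSO. RNA or reads of another cell source may contribute, so the changes below need not be responses of the lymphoma cells. In the deposited normalisation genes of cholesterol synthesis were lower with MS8815, as were genes of B-cell identity, DNA replication and mitosis. Genes of epithelial, fibroblast and other adherent cells, polycomb-regulated developmental genes, interferon-response genes and mitochondrially encoded transcripts were higher. Limma's camera test called 24 of these and other lists at its preset correlation and 0 with an estimated inter-gene correlation (adjusted p of 0.188 or more). The latter test has 2 residual degrees of freedom here and low power. Fry called 37 of 38 lists, among them cholesterol synthesis (adjusted p = 0.0013) and the pan-B list (adjusted p = 0.000533). HMGCS1, which makes HMG-CoA for the mevalonate pathway (GRCh38 chromosome 5, 43289395 to 43313512), had a normalised read count of 1964 ± 178.5 with MS8815 and 5611 ± 102.3 with DMSO (SD, n = 2 each). KRT8, an epithelial keratin (chromosome 12, 52897187 to 52949954), had 3261 ± 19.94 with MS8815 and 195.4 ± 4.779 with DMSO (SD, n = 2 each). At an adjusted p under 0.05, limma called 8782 of 18744 genes changed, 4589 higher and 4193 lower. A change of at least 2-fold was seen in 3604 of the higher and 455 of the lower genes. The 2 libraries of each group did not overlap for 73.7% of genes, against 33.3% by chance.

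How many of these genes counted as higher depended on the scaling and on the genes kept. The share was 52.3% in the deposited normalisation, 40.6% (3709 of 9126) after quantile normalisation, 31.3% (1831 of 5856) with the lower 50% of genes by level removed, and 98.8% (13291 of 13455) when the libraries were scaled to B-cell genes. The 23 B-cell genes used for that scaling had a median log2 fold change of -1.0 (SD 0.38, range -2.22 to -0.43). The median of all genes was 0 as deposited, -0.2 after quantile normalisation and 0.977 after scaling to B-cell genes. Without DMSO replicate 1 the count of changed genes was 3657, and without DMSO replicate 2 it was 3583.

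In the cholesterol synthesis list, 19 of 20 genes fell and none rose, with a median log2 fold change of -0.76 (adjusted p = 1.14e-08, and adjusted p = 0.188 with an estimated correlation). Besides HMGCS1 (-1.52 ± 0.07, SE, adjusted p = 3.28e-05), the fall covered SQLE, the squalene epoxidase (-1.30 ± 0.06), and the isopentenyl diphosphate isomerase IDI1 (-1.31 ± 0.06). In the same libraries adherent-cell genes had a median of 4.13 and the B-cell genes used for scaling one of -1.0, and after scaling to the latter the cholesterol list median was 0.24, with 13 genes higher and 3 lower. HMGCS1 was then lower at -0.51 (adjusted p = 0.00186) and SQLE at -0.29 (adjusted p = 0.00514). These p-values from limma take the scaling factor as exact, although the B-cell genes behind it had an SD of 0.38. SREBF2, which encodes the sterol-responsive transcription factor SREBP2 (chromosome 22, 41833079 to 41907308), fell by 0.60 in log2 as deposited. It was at -0.26 after quantile normalisation (adjusted p = 0.0047) and higher by 0.41 after scaling to B-cell genes. INSIG1, which holds back SREBP activation, had -0.23 as deposited, -0.03 after quantile normalisation and 0.77 after scaling to B-cell genes, with an adjusted p of 0.166 without DMSO replicate 1, 0.115 without DMSO replicate 2 and 0.0524 without MS8815 replicate 2. The list of sterol uptake and SREBP2 regulation had 4 of 12 genes higher and 4 lower (adjusted p = 0.587).

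EZH2 mRNA (chromosome 7, 148807383 to 148884321) had a log2 fold change of -0.27 ± 0.06 (SE, n = 2 each, adjusted p = 0.0123), which was -0.04 after quantile normalisation (adjusted p = 0.593) and 0.73 after scaling to B-cell genes. Its adjusted p was 0.0722 without DMSO replicate 1, 0.131 without DMSO replicate 2 and 0.0649 without MS8815 replicate 2. EED, a core subunit of the same complex, was at -0.90 ± 0.17 as deposited, with an adjusted p of 0.0926 without DMSO replicate 1 and 0.108 without DMSO replicate 2, and at 0.10 after scaling to B-cell genes. After quantile normalisation EED was at -1.53 (adjusted p = 0.00191). EZH2 protein was not analysed here. In the list of reported EZH2-repressed genes, 11 of 14 rose and 3 fell, with a median of 3.13 (adjusted p = 0.0038, and adjusted p = 0.188 with an estimated correlation). The cell-cycle inhibitor CDKN1A rose by 3.73 ± 0.14, while CDKN2A fell by 0.92. Of 25 polycomb-regulated developmental genes, 18 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 3.37 (adjusted p = 2.46e-05, and adjusted p = 0.188 with an estimated correlation). After scaling to B-cell genes, where most genes rise, the adjusted p of the polycomb list was 0.408. GATA6 rose by 4.29 ± 0.27 and KLF4 by 4.22 ± 0.36. Both rises lie near the adherent-cell median of 4.13 in these libraries, so they do not separate release of silenced genes from another RNA source. The plasma-cell regulator PRDM1 rose by 2.16 ± 0.34, and was at 0.84 after quantile normalisation (adjusted p = 0.0824), 2.01 without DMSO replicate 1 (adjusted p = 0.073) and 2.31 without DMSO replicate 2 (adjusted p = 0.0613). In the same libraries, markers of epithelial cells and fibroblasts had a median of 2.97 (7 of 10 rose, none fell, adjusted p = 0.000904, which was 0.285 after scaling to B-cell genes, and adjusted p = 0.204 with an estimated correlation), with KRT8 at 4.05 ± 0.08, KRT18 at 4.07 ± 0.12 and the intermediate filament gene VIM at 1.53 ± 0.03. Of 38 adherent-cell genes in a list added after the data were examined, 36 rose and 2 fell, with a median of 4.13.

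B-cell genes were lower in the libraries in which adherent-cell genes had that median of 4.13. In the pan-B list 9 of 11 fell and none rose (10 fell adjusted over the list alone), with a median of -1.0 (adjusted p = 3.96e-06, and adjusted p = 0.188 with an estimated correlation). The pan-B median was 0 after scaling to B-cell genes, a set that includes members of this list. VPREB3, a pre-B-cell receptor component, fell by 2.22 ± 0.08, and MS4A1, which encodes CD20, by 1.29 ± 0.04. Of 16 germinal-centre genes 13 fell and 1 rose (median -0.86, adjusted p = 3.96e-06, and 0.188 as the adjusted p with an estimated correlation), among them IRF8 at -1.43 ± 0.06 and RGS13 at -1.45 ± 0.05. B-cell receptor signalling genes had 11 of 15 lower and 1 higher, with a median of -0.84. Immunoglobulin genes, a list added later, had 6 of 7 lower and a median of -1.14. T-cell and NK-cell markers did not rise in any of 6 genes (2 fell, median -0.46, adjusted p = 0.408). The falls in DNA replication genes (18 of 20, median -0.59), mitosis genes (16 of 18, with 1 higher, median -0.67) and genes of MYC and ribosome biogenesis (18 of 19, median -0.54) had adjusted p-values of 1.4e-08, 3.53e-08 and 1.4e-08, each with an adjusted p of 0.188 with an estimated correlation. All of these medians were above 0 after scaling to B-cell genes, at 0.41, 0.34 and 0.46. Camera at the preset correlation also called the DNA replication and mitosis lists with EPZ-6438 (adjusted p = 0.019 and 0.0263). With MS8815N the values from camera were 6.53e-05 and 1.36e-05. None of these kept the call after quantile normalisation (0.9 and 0.9 with EPZ-6438, 0.146 and 0.0561 with MS8815N). MYC itself was at -0.47 ± 0.06 as deposited, -0.17 after quantile normalisation (adjusted p = 0.0574) and 0.53 after scaling to B-cell genes.

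**Figure D1:**
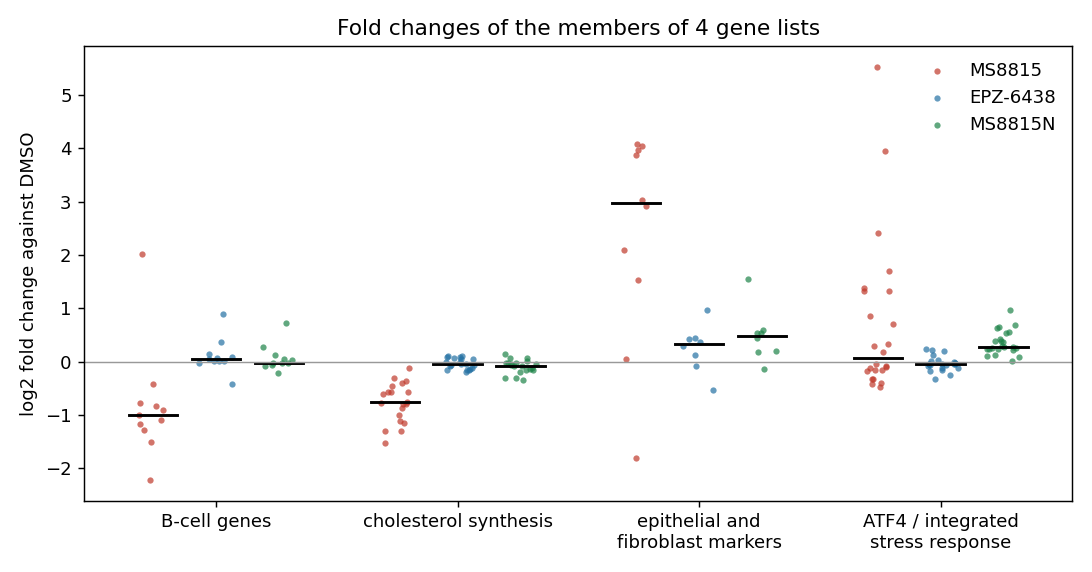
Log2 fold change against DMSO (vertical axis) of the members of 4 gene lists, for MS8815 (red), EPZ-6438 (blue) and MS8815N (green). Each point is a gene and each black line the list's median. With MS8815 the medians are -1.0 for B-cell genes, -0.76 for cholesterol synthesis and 2.97 for epithelial and fibroblast markers (0, 0.24 and 3.96 after scaling to B-cell genes); the ATF4 list has a median of 0.28 with MS8815N.

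The interferon list had 15 of 22 genes higher with MS8815 and 2 lower, with a median of 2.73 (adjusted p = 0.000505, which was 0.113 after scaling to B-cell genes, and adjusted p = 0.188 with an estimated correlation), among them IFIT1 at 4.78 ± 0.24. MHC class I genes had 12 of 14 higher and 1 lower, with a median of 1.21 (adjusted p = 2.02e-05, and adjusted p = 0.188 with an estimated correlation). HLA-B rose by 3.75 ± 0.10. HIF targets had 15 of 19 higher and 1 lower, with a median of 1.28 (adjusted p = 3.96e-06, and adjusted p = 0.188 with an estimated correlation), among them VEGFA at 4.51 ± 0.27. All 13 mitochondrially encoded transcripts rose, with a median of 1.65 (adjusted p = 1.05e-11, and adjusted p = 0.248 with an estimated correlation), whereas 16 of 19 nuclear genes of oxidative phosphorylation fell, with a median of -0.49 that was 0.51 after scaling to B-cell genes. These rises came beside the adherent-cell median of 4.13 and a median of 4.11 for non-polyadenylated RNAs (11 of 11 higher, for example RN7SL1 at 4.14 ± 0.03).

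Of the genes with the largest rises, HSPA6 and HSPA1A encode inducible heat-shock proteins of the HSP70 family. HSPA6 rose by 7.66 ± 0.25 in log2 and HSPA1A by 5.69 ± 0.36. The others, RNU1-28P, RNU1-1 and RNU1-3 (each listed at 0 in both DMSO libraries) and 7SK (listed at 0 in 1 DMSO library), are non-coding RNA genes with many near-identical copies, so the assignment of their reads is uncertain. The size of these 4 rises depends on the pseudocount, for example 8.61 for RNU1-1 with a pseudocount of 1 and 11.93 with 0.1. RNU1-3 was not called when either DMSO replicate was left out. The largest falls were in U2AF1, which has a near-identical copy in the build and is uncertain for the same reason (-3.12 ± 0.22), PLD4 (-2.89 ± 0.27), VPREB3, FAM65B (-2.12 ± 0.15), HTR3A (-2.04 ± 0.11) and MUM1 (-2.03 ± 0.13). All 6 were also called lower after scaling to B-cell genes, at -2.13 to -1.03. That scaling adds about 1 to each value, so genes chosen for falls this large stay below 0 by construction, and this is no independent check.

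**Figure D2:**
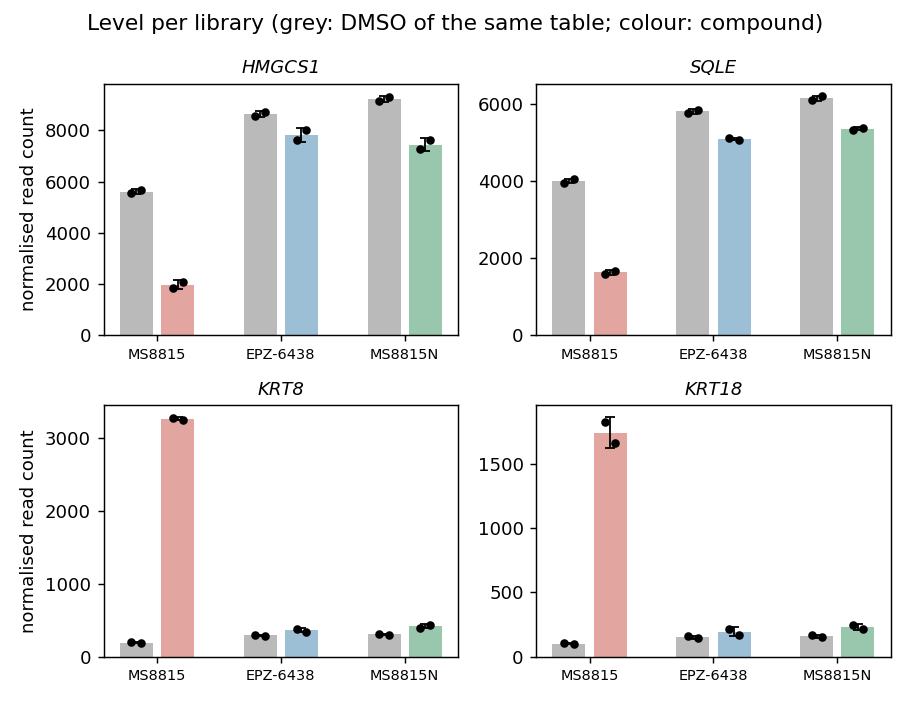
Normalised read count per library (vertical axes, from 0) of 2 cholesterol synthesis genes and 2 keratins. Points are libraries, bars means of 2 and error bars SD; grey bars are the DMSO libraries in the table of the named compound, and levels compare only within a pair because each table has its own normalisation. HMGCS1 was at 1964 against 5611 and KRT8 at 3261 against 195.4 in the MS8815 table.

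The comparison of EPZ-6438 with DMSO asks what inhibition of the EZH2 enzyme does over the same time. SYNE2, which encodes a nuclear envelope spectrin-repeat protein (chromosome 14, 63852983 to 64226433), rose by 0.51 ± 0.04 in log2 (6862 ± 65.07 against 4823 ± 193.1 normalised counts, SD, n = 2 each, adjusted p = 0.026). HERC1, a ubiquitin ligase gene, rose by 0.46 ± 0.04 (adjusted p = 0.0403). FRYL fell by 0.46 ± 0.04 (adjusted p = 0.0463, which was 0.0709 after quantile normalisation and 0.0512 with a replicate block) and CAND1, a regulator of cullin ligases, by 0.32 ± 0.02 (adjusted p = 0.026). Limma called 6 of 18320 genes, 3 higher and 3 lower, with 3076 at an unadjusted p under 0.05. The other 2, HIST2H3A and HIST2H3C, fall outside the naming rule and were chosen after their values were seen; each is listed at 0 in one group, and they are near-identical copies whose reads cannot be assigned with certainty. With the lower 50% of genes by level removed, limma called 283 genes (64 higher and 219 lower), and without trend 169 (48 higher and 121 lower). Limma on log2 counts called 25 genes and the joined fit 0, and without either DMSO or either EPZ-6438 library the count was 0.

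EZH2 mRNA had a log2 fold change of 0.02 ± 0.04 with EPZ-6438 (adjusted p = 0.86), HMGCS1 of -0.14 ± 0.04 (adjusted p = 0.129), SQLE of -0.19 ± 0.03 (adjusted p = 0.0881) and CDKN1A of 0.38 ± 0.17 (adjusted p = 0.345). No cholesterol synthesis gene was called (4 lower adjusted over the list alone), and the list's median was -0.05 (0.01 after quantile normalisation, adjusted p = 0.0781 as deposited). None of 13 reported EZH2-repressed genes was called, with a median of 0.23 (adjusted p = 0.0855). The MHC class I list had the smallest adjusted p among the lists fixed before the data were examined, with a median of 0.49 and no gene called (6 of 14 higher adjusted over the list alone, adjusted p = 0.00017, and adjusted p = 0.49 with an estimated correlation). HLA-B was at 0.71 ± 0.11 (adjusted p = 0.0808). Mitochondrially encoded transcripts had a median of -0.10 (adjusted p = 0.000324, 0.0518 without EPZ-6438 replicate 1, and an adjusted p of 0.528 with an estimated correlation). Adherent-cell genes had a median of 0.39 in these libraries, with none of 38 called. The MHC class I median of 0.49 lies near it, and whether reads of the same source give that rise was not tested.

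The comparison of MS8815N with DMSO asks what the analog control does by itself. In a list of the ATF4 program, the transcriptional arm of the integrated stress response, 10 of 23 genes rose and none fell. ATF5, a transcription factor of this response (chromosome 19, 49928702 to 49933935), had a normalised read count of 14260 ± 93.43 with MS8815N and 7333 ± 17.5 with DMSO (SD, n = 2 each), a log2 fold change of 0.96 ± 0.03 (adjusted p = 0.000119). The asparagine synthetase ASNS rose by 0.69 ± 0.05 and the serine-synthesis enzyme PSAT1 by 0.63 ± 0.03. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, which is not in the list, rose by 1.05 ± 0.06. With any 1 of the 4 libraries left out, ASNS was at 0.64 to 0.74 and PCK2 at 1.01 to 1.09. Neither gene was then called. Adjusted over the ATF4 list alone, 18 rose and none fell, with a list median of 0.28 (adjusted p = 1.24e-21, and adjusted p = 0.347 with an estimated correlation). The transfer-RNA synthetase genes, a list added later, had 3 of 19 higher, WARS, SARS and GARS, with a median of 0.10.

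Limma called 98 of 18398 genes with MS8815N, 53 higher and 45 lower (2894 at an unadjusted p under 0.05). The share of higher genes was 54.1% as deposited, 31.6% (123 of 389) with the lower 50% of genes by level removed, 33.3% (84 of 252) without trend, 32.6% (115 of 353) with a replicate block, 67.7% in the joined fit (65 genes) and 80% after scaling to B-cell genes. With a library left out, which also leaves fewer degrees of freedom, the count was 2 without DMSO replicate 1, 6 without DMSO replicate 2, and 0 without MS8815N replicate 1 or without MS8815N replicate 2, although the ATF4 list kept an adjusted p of 5.06e-16 or less in each case at the preset correlation. The log2 fold change of ATF5 was 0.95 without MS8815N replicate 1 (adjusted p = 0.0989) and 0.97 without MS8815N replicate 2 (adjusted p = 0.182), beside 0.96 with all libraries.

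Other genes among the largest rises were MICAL2 (1.10 ± 0.13) and THBS1 (0.85 ± 0.11). MICAL2 and THBS1 are adherent-cell genes that also rose with MS8815, by 4.34 and 4.24, and the adherent-cell list had a median of 0.44 with MS8815N, with 1 of 38 genes called (18 higher and 1 lower adjusted over the list alone). Falls were largest in RBM14-RBM4, a readthrough gene that overlaps its neighbours (-1.35 ± 0.19), FRYL (-0.57 ± 0.05), ALMS1 (-0.55 ± 0.07), KCNAB2 (-0.44 ± 0.06), HDAC9 (-0.44 ± 0.05) and LPCAT1 (-0.42 ± 0.03). Of these rises and falls, the call was lost in the joined fit for MICAL2 (adjusted p = 0.0502), THBS1 (0.0601), RBM14-RBM4 (0.419), ALMS1 (0.0601), KCNAB2 (0.609) and HDAC9 (0.0765), for ALMS1 also after quantile normalisation (0.0638) and after scaling to B-cell genes (0.0543), and for all 8 genes when any 1 of the 4 libraries was left out (0.0509 to 0.448). Of the cholesterol synthesis genes, 2 of 20 fell (1 higher and 5 lower adjusted over the list alone), among them HMGCS1 by 0.31 ± 0.04 (adjusted p = 0.0236, which was 0.0554 after quantile normalisation, 0.093 in the joined fit and 0.137 to 0.443 when any 1 of the 4 libraries was left out). The list's median was -0.08 (adjusted p = 0.000157, and adjusted p = 0.427 with an estimated correlation). SREBF2 was at -0.04 ± 0.03 (adjusted p = 0.485), EZH2 at -0.03 ± 0.04 (adjusted p = 0.79) and CDKN1A at 0.48 ± 0.14 (adjusted p = 0.178). MHC class I genes had a median of 0.39 with none called (8 of 14 higher adjusted over the list alone, adjusted p = 1.72e-05, and adjusted p = 0.347 with an estimated correlation). That median lies near the 0.44 of the adherent-cell list, and whether reads of the same source give it was not tested. Of the mitochondrially encoded transcripts 4 of 13 rose, with a median of 0.11 (8 higher and 1 lower adjusted over the list alone, adjusted p = 1.63e-08, and adjusted p = 0.427 with an estimated correlation), for example MT-CO1 at 0.30 ± 0.02.

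The compounds were next compared with each other at the same dose and time, in joined fits chosen after the data were examined. Between the analog control and the enzymatic inhibitor, MS8815N gave higher transcripts of part of the ATF4 list. ATF5 was higher by 1.01 (95% interval 0.93 to 1.10, adjusted p = 4.72e-05), ASNS by 0.72 (0.51 to 0.94) and PSAT1 by 0.71 (0.62 to 0.79), and PCK2, which is not in the list, by 0.91 (0.70 to 1.11). In the ATF4 list 8 of 23 genes were higher with MS8815N and none lower (20 and 0 adjusted over the list alone), with a median of 0.33 (adjusted p = 7.04e-38, and adjusted p = 0.00493 with an estimated correlation). Mitochondrially encoded transcripts had 5 of 13 higher (13 adjusted over the list alone), with a median of 0.22 (adjusted p = 7.94e-35, and adjusted p = 0.109 with an estimated correlation). No difference was called for EZH2 (-0.05, -0.15 to 0.06), SREBF2 (0.03, -0.05 to 0.11), SQLE (-0.01, -0.10 to 0.09) or HMGCS1 (-0.17, -0.31 to -0.03, adjusted p = 0.71). The cholesterol synthesis list had a median difference of -0.08 with no gene called (adjusted p = 0.0154, which was 0.155 after scaling to B-cell genes, 0.134 without EPZ-6438 replicate 1, 0.177 without MS8815N replicate 2, and an adjusted p of 0.32 with an estimated correlation). In all, limma called 30 of 17467 genes, 29 higher and 1 lower with MS8815N (1069 at an unadjusted p under 0.05). Limma without trend called 4, with an adjusted p of 0.147 for PSAT1, 0.333 for PCK2 and 0.535 for ASNS. ATF5 and PSAT1 kept the call with each library left out, whereas PCK2 (adjusted p 0.0615 to 0.163) and ASNS (0.138 to 0.341) lost it when any 1 DMSO, EPZ-6438 or MS8815N library was left out, and ASNS was at 0.0787 after quantile normalisation. The count was 73 without the MS8815 libraries, 11 without DMSO replicate 1 or without DMSO replicate 2, 60 without MS8815 replicate 1 or without MS8815 replicate 2, 8 and 10 without EPZ-6438 replicate 1 and 2, and 8 and 11 without MS8815N replicate 1 and 2.

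**Figure D3:**
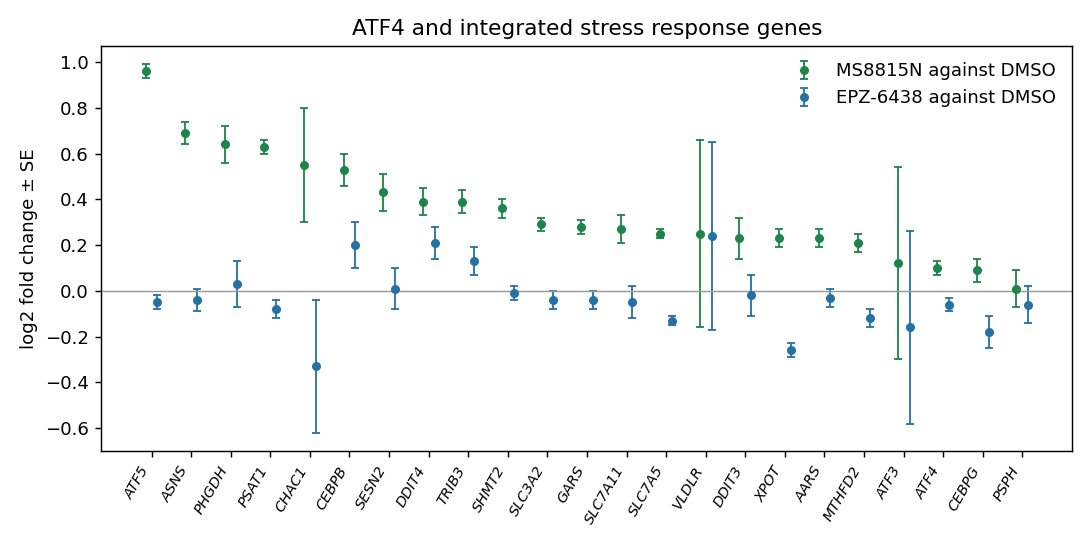
Log2 fold change against DMSO (vertical axis) of the 23 tested ATF4-program genes, for MS8815N (green) and EPZ-6438 (blue). Points are estimates from 2 libraries per group and bars are standard errors; the median is 0.28 with MS8815N and -0.04 with EPZ-6438 (0.34 and -0.02 after scaling to B-cell genes).

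MS8815 differed from both other compounds in many genes. Against MS8815N, limma called 8814 of 17467 genes, 4258 higher and 4556 lower with MS8815 (48.3% higher, 37.1% after quantile normalisation, 28.5% with the lower 50% of genes removed and 98.3% after scaling to B-cell genes). Against EPZ-6438 it called 8813, 4247 higher and 4566 lower (48.2% higher, and 37.3%, 29.7% and 98.2% in the same order). With only the 4 libraries compared, the counts were 7509 against MS8815N and 7367 against EPZ-6438. The joined fit takes 1 spread per gene for all groups, although the MS8815 replicates differed more (median 0.143 against 0.079 to 0.085). Its intervals for MS8815 may therefore be too narrow. HMGCS1 with MS8815 differed from MS8815N by -1.20 (95% interval -1.34 to -1.06) and from EPZ-6438 by -1.37 (-1.51 to -1.23), and SQLE by -1.09 (-1.19 to -1.0) and -1.10 (-1.19 to -1.01). In the cholesterol synthesis list 18 and 19 of 20 genes were lower, with medians of -0.69 and -0.74 (adjusted p = 7.43e-08 and 2.17e-08, and adjusted p = 0.0418 and 0.0356 with an estimated correlation). After scaling to B-cell genes these medians were 0.24 and 0.26, with 13 genes higher in each and 3 and 4 lower. The medians of all genes were then 0.88 and 0.925, and camera placed the list below the other genes (direction down, adjusted p = 0.0267 and 0.0178). The B-cell genes used for scaling had median differences of -0.94 and -0.99 in these comparisons, and adherent-cell genes 3.64 and 3.70. EZH2 mRNA differed by -0.24 (-0.34 to -0.13) from MS8815N and by -0.28 (-0.39 to -0.18) from EPZ-6438, both smaller in size than the B-cell medians. ATF5 with MS8815 differed from MS8815N by -1.28 (-1.36 to -1.20), also in the presence of that lower B-cell median.

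Across the 17467 shared genes, the log2 fold changes of EPZ-6438 and MS8815N against DMSO had a Pearson r of 0.563 (Spearman 0.551). Unchanged groups compared with shared controls gave a simulated r of 0.501. For MS8815 the r was 0.366 with EPZ-6438 (Spearman 0.35, simulated 0.501) and 0.411 with MS8815N (Spearman 0.395, simulated 0.499). The covariances were 0.145, 0.285 and 0.312 in the same order, each against a simulated 0.115. With 1 DMSO library for each comparison of a pair, in both arrangements, the r was 0.055 and 0.073 for EPZ-6438 and MS8815N, 0.166 and 0.175 for MS8815 and EPZ-6438, and 0.201 and 0.203 for MS8815 and MS8815N (covariances 0.021 to 0.0272, 0.159 to 0.169 and 0.189 to 0.193). The covariance of EPZ-6438 and MS8815N thus fell from 0.145 to 0.0272 or less, so most of it came with the shared controls. For the MS8815 pairs a smaller part of the covariance was lost. Among genes low with DMSO and abundant with MS8815, 108 lay at 3.6 to 4.6 in log2 with MS8815. These had medians of 0.44 with EPZ-6438 and 0.48 with MS8815N, which adds to the covariance of the MS8815 pairs. How much it adds was not tested, so the rest need not be a shared response to the compounds. Of the genes called with MS8815N, 26 were higher and 37 lower with MS8815 too, and 8 were called in opposite directions. Independent calls would give 11.88 and 10.66 for the first 2 counts, and as many top genes of simulated unchanged groups against shared controls gave 42.57 and 37.09. In that simulation MS8815 changed nothing, whereas 8782 genes were called with MS8815 in the data. The simulated overlaps and r for the MS8815 pairs are therefore no measure of what shared controls gave there. EPZ-6438 and MS8815N shared 1 higher and 3 lower genes, against 0.01 and 0.01 for independent calls and a simulated 0.51 and 0.4 (highest 3 and 2 in 100 simulations). Of the 3 lower genes, 1 is HIST2H3A or HIST2H3C, whose reads cannot be assigned with certainty.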

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

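Alternatives chosen after the data were examined were the log2 fits, the joined fit for comparisons with DMSO, the removal of the MS8815 libraries, the scaling to B-cell genes, the split of the controls and the filter at a mean of 50. With a replicate left out, the lone remaining library of a group is assumed to vary like the others. Restricting the fit to the 4 libraries compared is identical to the fit used for each comparison with DMSO, and leaving out trend or adding a replicate term leaves the fold changes behind the correlations unchanged by construction. Of 778 values of single genes under alternatives that keep all libraries, 718 kept their direction and their side of the threshold, 36 lost and 11 gained the call, and 13 changed sign. Of 535 results of list tests, 342 kept direction and side, 156 lost the call, 23 changed direction, and 14 were numbers of lists called that moved by over 1.5 times. With a library left out, 365 of 480 gene values kept direction and side, 110 lost the call, 1 gained it and 4 changed sign; of 652 list results, 601 kept them, 47 lost the call and 4 numbers of lists moved. Where no cause is given below, the cause was not tested. In 10 simulations of the MS8815 table, run after the data were examined, 1.5-fold changes were recovered for 24.4% of genes (range 0 to 34.8%), with 5% in the lower and 43.2% in the upper 50% of genes by level. With the MS8815 libraries at the DMSO depth these were 55% (47 to 62%), 27.8% and 81.5%, so in these simulations fewer reads limited the calls at both levels. The dispersion was again that of the DMSO libraries.

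Genes changed under a fold threshold of at least 1 in log2, which is stricter by construction, numbered 4059 for MS8815 vs DMSO, 2 for EPZ-6438 vs DMSO, 15 for MS8815N vs DMSO, 3448 for MS8815 vs MS8815N, 3466 for MS8815 vs EPZ-6438 and 2 for MS8815N vs EPZ-6438. At an adjusted p under 0.01 the smaller counts became 0 for EPZ-6438 vs DMSO, 20 for MS8815N vs DMSO and 9 for MS8815N vs EPZ-6438. With the lower 50% of genes removed, which leaves fewer genes to test, they were 283 for EPZ-6438, 389 for MS8815N, 5720 for MS8815 vs MS8815N and 5678 for MS8815 vs EPZ-6438, and the correlations of fold changes were 0.504 for MS8815 and EPZ-6438, 0.552 for MS8815 and MS8815N and 0.678 for EPZ-6438 and MS8815N. Limma without trend called 169 genes for EPZ-6438, 252 for MS8815N and 4 for MS8815N vs EPZ-6438. With a replicate block it called 10 for EPZ-6438 and 353 for MS8815N, but deviations of replicate 1 correlated between groups by only -0.054 to 0.042 across genes, so the numbers do not pair the libraries. On log2 counts EPZ-6438 had 25 genes with a pseudocount of 1, 26 with 5 and 9 with 0.1, and in the joined 8 libraries it had 0 and MS8815N 65. Quantile normalisation gave 13 for EPZ-6438 and 17 for MS8815N vs EPZ-6438. Without the MS8815 libraries, the last comparison had 73.

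Scaling to B-cell genes gave 13455 genes for MS8815 vs DMSO, 13279 against MS8815N, 13416 against EPZ-6438 and 59 for MS8815N vs EPZ-6438. Since it adds about 1 to each log2 fold change of MS8815 vs DMSO, smaller falls changed sign by construction: EZH2 to 0.73, EED to 0.1, SUZ12 to 0.8, SREBF2 to 0.41, INSIG1 to 0.77 and MYC to 0.53. With MS8815N the same scaling put EZH2 at 0.03, SREBF2 at 0.02 and MYC at 0.05, none of them called. Direction of a list is camera's, relative to the other genes, so a list median can change sign without it, as for cholesterol synthesis with MS8815 (0.24 after this scaling) and replication-dependent histones (-0.47 after quantile normalisation). Lists that changed camera's direction under scaling to B-cell genes had adjusted p-values, for MS8815 vs DMSO, of 0.285 for DNA replication, 0.705 for mitosis, 0.0711 for MYC and ribosome biogenesis, 0.563 for the unfolded protein response, 0.0333 for nuclear oxidative phosphorylation, 0.149 for VHL ligase subunits and 1.61e-09 for ribosomal proteins. Against MS8815N these were 0.132, 0.384, 0.109, 0.0367 for oxidative phosphorylation, 0.151 for VHL ligase subunits and 2.4e-10 for ribosomal proteins. Against EPZ-6438 they were 0.0993, 0.293, 0.0652, 0.0124 for oxidative phosphorylation and 2.81e-10 for ribosomal proteins. Glycolysis with MS8815N had 0.975. After quantile normalisation SUZ12 was at 0 with MS8815, and with MS8815N EZH2 was at 0.02, SREBF2 at 0.01 and MYC at 0.05. Lists that changed camera's direction under quantile normalisation were ribosomal proteins (0.557 for MS8815 vs DMSO, 0.742 for MS8815 vs EPZ-6438), mitosis (0.9) and proteasome subunits (0.81), the last pair with EPZ-6438.

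The numbers of lists called were 24 for MS8815, 8 for EPZ-6438 and 16 for MS8815N vs DMSO, 23 for MS8815 vs MS8815N, 22 for MS8815 vs EPZ-6438 and 8 for MS8815N vs EPZ-6438. With an estimated inter-gene correlation they were 0, 0, 0, 9, 9 and 1, and with fry 37, 0 and 9 vs DMSO, then 36 and 37 for MS8815 against the other compounds. EPZ-6438 had 5 after quantile normalisation and 3 after scaling to B-cell genes, and MS8815N had 10 after quantile normalisation.

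With each library left out in turn, genes changed ranged from 3583 to 8932 for MS8815 vs DMSO (lowest without a DMSO library), were 0 in every case for EPZ-6438, and ranged from 0 to 6 for MS8815N and from 8 to 60 for MS8815N vs EPZ-6438. Lists called ranged from 3 to 12 for EPZ-6438, from 9 to 13 for MS8815N and from 5 to 9 for MS8815N vs EPZ-6438. The correlation of EPZ-6438 and MS8815N ranged from 0.459 to 0.712. With the DMSO libraries split 1 and 1 between the comparisons, which removes the shared controls, correlations were 0.055 and 0.073 for that pair, 0.166 and 0.175 for MS8815 and EPZ-6438, and 0.201 and 0.203 for MS8815 and MS8815N. Uncalled genes that changed sign were EZH2 (-0.02 to 0.06) with EPZ-6438, and EZH2 (-0.07 to 0.01), PRDM1 (-0.59 to 1.73) and MYC (-0.04 to 0.01) with MS8815N.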

Other observations

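Other gene groups moved in the MS8815 libraries as well, beside the adherent-cell median of 4.13. Targets of NRF2, the oxidative-stress regulator, had 9 of 11 higher and a median of 1.12 (adjusted p = 8.51e-06, and adjusted p = 0.188 with an estimated correlation), among them the ferritin light chain FTL at 1.25 ± 0.03. Lysosome genes had 14 of 19 higher and 2 lower (median 0.76, adjusted p = 3.37e-05, and adjusted p = 0.196 with an estimated correlation), for example cathepsin D, CTSD, at 2.70 ± 0.04. Proteasome subunits had 14 of 16 higher, with a median of 0.29 (adjusted p = 1.61e-05, and adjusted p = 0.188 with an estimated correlation). Immediate early genes had 8 of 10 higher and 1 lower (median 2.58, adjusted p = 0.00213, and adjusted p = 0.188 with an estimated correlation), among them JUN at 3.01 ± 0.09. Heat-shock genes split, with HSPA1B at 2.4 ± 0.05 and HSPA8, the constitutive HSP70, at -0.83 ± 0.02 (5 higher and 5 lower of 12, adjusted p = 0.914); after scaling to B-cell genes 10 were higher and none lower. The unfolded protein response had 7 of 15 lower and 3 higher (median -0.23, adjusted p = 0.00439, and adjusted p = 0.188 with an estimated correlation), with HSPA5 at -0.93 ± 0.03, and its median was 0.78 after scaling to B-cell genes (adjusted p = 0.563, and 0.264 after quantile normalisation). Ribosomal protein genes had 18 of 30 lower and a median of -0.17 (adjusted p = 1.34e-05, and adjusted p = 0.488 with an estimated correlation), which was 0.03 after quantile normalisation and 0.84 after scaling to B-cell genes. The subunits of the VHL ubiquitin ligase, which many PROTACs recruit, had 2 of 5 lower (median -0.23, adjusted p = 0.0455, and adjusted p = 0.284 with an estimated correlation), and a median of 0.77 after scaling to B-cell genes (adjusted p = 0.149, and 0.731 after quantile normalisation). Replication-dependent histones had 7 of 15 higher and a median of 0.72 (adjusted p = 0.00302, and adjusted p = 0.188 with an estimated correlation), which was -0.47 after quantile normalisation (adjusted p = 0.583, and 0.281 after scaling to B-cell genes).

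In the MS8815N libraries the transcription factor XBP1 rose by 0.46 ± 0.06 (adjusted p = 0.0407) and FTH1, the ferritin heavy chain, by 0.24 ± 0.02 (adjusted p = 0.016). The muscle-type phosphofructokinase PFKM fell by 0.31 ± 0.04 (adjusted p = 0.0265) and the immunoglobulin heavy chain gene IGHG1 by 0.27 ± 0.01 (adjusted p = 0.00443). Against EPZ-6438, FTH1 was higher by 0.23 (95% interval 0.18 to 0.28) and the chaperone genes CALR and HSPA5 by 0.20 ± 0.02 and 0.14 ± 0.02. The unfolded protein response list then had 2 of 15 higher and the NRF2 list 2 of 11, with medians of 0.11 and 0.14 (adjusted p = 1.28e-08 and 1.48e-07, and adjusted p = 0.0525 for each with an estimated correlation).

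Tests chosen only after the result was seen were those on the adherent cell source in the MS8815 libraries, on non-polyadenylated RNA, on both explanations for the cholesterol genes and on the authors' normalisation for the ATF4 list; the other 2, on release of EZH2-silenced genes and on the adherent source for the ATF4 list, were fixed before their results.

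Non-lymphoid genes were far higher in the MS8815 libraries. Carry-over of non-polyadenylated RNA as the whole cause is argued against by the epithelial and fibroblast list, made of polyadenylated transcripts, at a median of 2.97. RNA or reads from one adherent cell source may contribute. Of 2034 genes at 50 to 200 normalised counts with DMSO, 138 lay at 3.6 to 4.6 in log2 fold change. The bands of that width below and above held 71 and 4, a second peak in a band set after the values were seen. Of 126 genes below 200 with DMSO and above 1000 with MS8815, 108 lay in that band (median fold 16.8), although that selection admits only large rises. In the same libraries 23 B-cell genes had a median of 49.9% of their DMSO level, which a mixture with other RNA could also give. Release of EZH2-silenced genes stays open too. The 39 genes of the polycomb lists exceeded 780 matched entries of like DMSO level, in which a gene can recur, by 2.29 (median 3.30, SD 1.59, against 1.01). Adherent cells may also express some of these genes. CDKN1A, given above with the EZH2-repressed genes, rose by 3.73, within the band of 3.6 to 4.6. With this overlap not tested over the whole lists, the excess does not separate release of silenced genes from another RNA source. The kit used for each library is not stated, so a batch of library preparation stays open as well.

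Cholesterol synthesis genes were lower in the MS8815 libraries by a median of -0.76. Dilution of lymphoma RNA by other RNA could give this fall, since the list median lay 0.24 above that of 23 B-cell genes. Lower cholesterol synthesis transcripts in the lymphoma cells cannot be told apart from it with these libraries: after scaling to B-cell genes the list median was 0.24, above 0, yet below that of the other genes (0.977 over all genes, camera direction down, adjusted p = 0.0025). What keeps it open is that the scaling is 1 factor for all genes and that the other source may express these genes too. HMGCS1 (-0.51) and SQLE (-0.29) were lower after scaling, while most genes of the list were higher. The 23 B-cell genes used for scaling had an SD of 0.38, and SQLE lay within that spread.

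The ATF4 list was higher with MS8815N by a median of 0.28. Reads of the adherent cell source are argued against as the whole cause, since they could give at most 11.7% of that median. This upper bound counts all MS8815 reads of each gene as the source's. A library-wide effect of the authors' normalisation is argued against too, since the median was 0.33 after quantile normalisation. Camera called the list at the preset correlation there (adjusted p = 2.78e-24) but not with an estimated correlation as deposited (adjusted p = 0.347). The latter has 2 residual degrees of freedom and low power, and fry gave an adjusted p of 0.00753 as deposited. Quantile normalisation was run on the already normalised values. It would leave factors that differ by gene and library in place, so such factors stay open. An effect of MS8815N itself stays open and untested beyond the comparison that showed it, since each group has 2 libraries whose independence is not stated.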
